A study of Mus musculus with 2 samples.

How the data were processed

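DNase-seq of mouse embryonic limb (11.5 days, strain B6NCrl, pooled sexes) was deposited for 2 biological replicates with 1 technical replicate each, per the labels. Per the labels and the deposited file descriptions, reads were aligned to mm10 and regions were called on the filtered alignment of each library, so peaks were called per library and not on pooled reads. The aligner, the region caller and their settings are not given in the sources used here. The labels name 2 instrument models for replicate 2 and none for replicate 1.

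The deposited peak lists hold intervals of 150 bp with a signal value per peak. The values are whole numbers from 2 to 150, some of them written with a decimal. Their scaling is not stated by the authors in the sources used here. This signal is the authors' own value and was used only to describe, rank or filter peaks within a list. The deposited hotspot lists hold wider intervals with a −log10 q value from 1.30 to 6 and then 100, which is read as a ceiling. No read counts were used here, so the depth of each library is unknown and no interval based on depth is given. Wilson and ratio intervals cover counting error over regions only, and neighbouring regions are not independent.

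Chromosome lengths of GRCm38 and the GENCODE M21 annotation were checked against the peak coordinates, and regions on all 21 named chromosomes ended within them. The annotation gave 21938 protein-coding genes with 54361 starts. Peaks on mitochondrial and unplaced sequences were left out of all comparisons. Overlap meant at least 1 bp. Overlaps were computed with NumPy in place of bedtools, which had been chosen beforehand, by the same definition. Shared peaks are merged overlapping peaks of both libraries. Chance placement used 100 circular shifts. A peak was promoter if its centre lay within 1 kb of a protein-coding start and distal otherwise, and a distal peak was assigned to the nearest start within 500 kb. Each of 15 gene lists with 282 genes was set against 10000 random lists of equal size, matched for distal peaks on deciles of the length of sequence nearest to a gene, and the percentile is a description of these libraries with no p-value. The central 150 bp of each peak were compared with windows 500 bp to either side for 36 words, which are consensus sites and 1 control word. A word was counted at a ratio of 1.5 or more only if its interval lay above 1. GC-matched windows were taken from 1421342 random windows without peaks.

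Groups, gene lists, sites, named genes and most alternatives were fixed before the data were examined. The ratio of 1.5 used to count sites and the central 95% used to count lists were chosen after values had been seen, as were the removal of peaks whose signal is written with a decimal, matching on promoter peaks and the gene families defined by symbol. Named genes were the 3 members of each of 4 limb lists and the 2 members of each other list with the most distal shared peaks, the 10 such genes genome-wide, 7 genes named in advance (Shh, Lmbr1, Hoxa13, Hoxd13, Tbx5, Tbx4 and Pitx1), the 5 strongest shared distal peaks, the 3 strongest private peaks and the 5 widest hotspots of each library. The result for 1 gene that this rule names is not reported here. Alternatives changed the overlap, peak threshold, promoter window, assignment, matching, motif background and window, and left out each replicate.

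The steps were tested on simulated data. Of 20000 simulated regions 60.1% were found overlapping where 60% were planted, all 1542 planted words were found in 5000 windows, 500 of 500 nearest starts equalled a direct search, and with 21938 genes 3 of 40 unchanged lists fell outside the central 95% and 39 of 40 lists with doubled counts lay above it. The simulated gene counts were Poisson, with a mean set only by the decile used for matching. They spread less than the real counts, so the result for doubled counts does not carry over to the real lists. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 were used.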

Results

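Open chromatin of the mouse limb was mapped at 11.5 days of embryonic development with DNase-seq, in which DNase I cuts accessible DNA and the cut ends are sequenced. At this stage the limb is a bud of mesenchyme covered by ectoderm, in which the skeletal pattern is being laid down. The labels give a single group, limb tissue from pooled male and female embryos of strain B6NCrl, with 2 biological replicates. No contrast between conditions was made, so the comparisons are of replicate with replicate and of regions with chance placement within these libraries. Read depth is unknown, because the lists used here hold no read counts. With 2 libraries no test between groups was possible, and intervals given below cover counting error over regions only.

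Replicate 1 held 174611 peaks and replicate 2 held 167550, or 171080 ± 4993 (SD, n = 2). Broader hotspots numbered 151790 and 144013 and covered 53.4 and 56.8 Mb of the named chromosomes. Of the peaks on chromosomes 1 to 19, X and Y, 69.8% in replicate 1 and 73.1% in replicate 2 overlapped a peak of the other library by at least 1 bp, or 71.5% on average. These are the 2 directions of 1 comparison and not independent measurements, so no SD is given. Circular shifts of the peaks along their chromosomes gave 1.94% on average over 100 shifts, and moves of each peak within 10 kb gave 5.83%. The overlapping peaks merged into 118637 shared regions, which are called shared peaks here. The rank correlation of peak values between replicates (Spearman rho of the deposited signal) was 0.905 over 126469 overlapping pairs. It is a correlation across regions, which are not independent replicates. For hotspots, whose deposited −log10 q reaches a ceiling, it was 0.565.

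Sharing followed the deposited signal of a peak. In the lowest decile of signal 26.2% of replicate 1 peaks and 24.4% of replicate 2 peaks were shared, and in the highest decile 98.8% and 98.9%. All peaks overlapped a hotspot of their own library, and 77.7% and 77.1% overlapped a hotspot of the other.

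**Figure D1:**
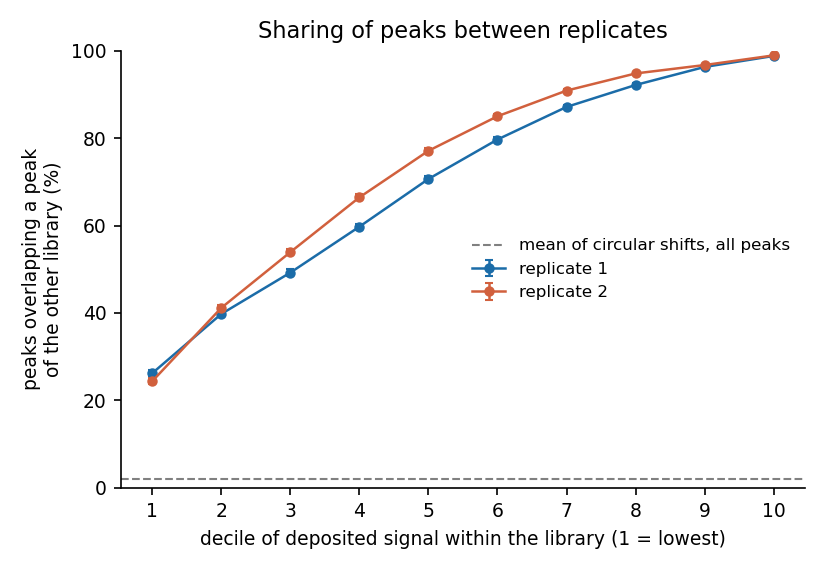
Percent of peaks in each library that overlap a peak of the other library (y axis), by decile of deposited signal within the library (x axis), with Wilson 95% intervals and the mean of circular shifts as a dashed line. From the lowest to the highest decile the share climbs from 26.2% to 98.8% in replicate 1 and from 24.4% to 98.9% in replicate 2.

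Shared peaks were concentrated at promoters. The centre of 23.4% of shared peaks (Wilson 95% interval 23.2 to 23.6) lay within 1 kb of a protein-coding start, against 2.54% after circular shifts. The libraries taken alone gave 22.3% and 21.5%, or 21.9% ± 0.556 (SD, n = 2). Introns held 36.9% of shared peaks and intergenic sequence 34.2%, against 40.9% and 52.3% after shifts. Coding exons held 1.46%, 3' UTRs 1.34% and 5' UTRs outside the promoter windows 0.104%. In the highest decile of signal 77.9% of shared peaks were promoter peaks, against 9.11% in the lowest.

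Transcription factors of the limb mesenchyme had many distal peaks, those more than 1 kb from any protein-coding start and assigned to the nearest start. The 35 genes of this list had a median of 27 distal shared peaks, against 7 in random lists matched on the length of sequence nearest to each gene, and the list lay above all 10000 of them. Lmx1b (chromosome 2, 33560965 to 33640511, mm10), which specifies dorsal identity in the limb, had 66 distal shared peaks. Meis1, a cofactor of Hox proteins expressed in the proximal limb, had 61, and Sall1, a zinc finger factor of limb and kidney development, had 53. Each library alone gave higher counts, since a shared peak needs both: 85.5 ± 3.54 (SD, n = 2) for Lmx1b, 98.5 ± 20.5 for Meis1 and 73.0 ± 7.07 for Sall1. When only peaks within 100 kb of a start were assigned, Lmx1b had 63, Meis1 21 and Sall1 16. Tbx5 (chromosome 5, 119832668 to 119885219), which is needed for forelimb outgrowth, had 35 distal shared peaks, and Tbx4 and Pitx1, factors of the hindlimb, had 30 and 21. In the libraries alone Tbx5 had 52.0 ± 7.07 (SD, n = 2), Tbx4 44.5 ± 9.19 and Pitx1 30.5 ± 3.54.

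Signals that pattern the limb bud stood above random lists as well. Their 25 genes had a median of 15 distal shared peaks against 7, at percentile 99.945, and a median of 22 in replicate 1 and 25 in replicate 2 alone. Wnt5a, a signal for outgrowth along the limb axis, had 55 distal shared peaks, Gli3, the transcription factor that mediates Hedgehog signalling, had 46, and Bmp2, a bone morphogenetic protein, had 42. In the libraries alone these were 72.5 ± 4.95 (SD, n = 2), 65.0 ± 1.41 and 59.5 ± 2.12, and within 100 kb of a start they were 25, 26 and 15. Cartilage and bone genes had a median of 10 against 3.5 (percentile 99.975), and included the chondrogenic factors Sox9 with 68 (103 ± 1.41 in the libraries alone, SD, n = 2), Sox6 with 60 (88.5 ± 7.78) and Sox5 with 58. Their order depended on the reach: within 100 kb of a start Sox6 had 44, Sox5 26 and Sox9 20. Sox9 lies on chromosome 11 from 112782224 to 112787760. Muscle lineage genes had a median of 9 against 3 (percentile 99.99). Among them Pax3, a marker of migrating muscle precursors, had 37 distal shared peaks and Eya1, a transcriptional cofactor, had 32, with 59 and 61 for Pax3 and 50 and 47 for Eya1 in replicate 1 and replicate 2 alone. Genes of the surface ectoderm and apical ridge had a median of 7 against 2.5 (percentile 99.93), and of 9.5 and 13 in replicate 1 and replicate 2 alone. Sp8, needed for the apical ridge, was at 25 and Tfap2c, an AP-2 factor, at 23 (43 and 31 in the libraries alone), and within 100 kb of a start they had 16 and 10.

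**Figure D2:**
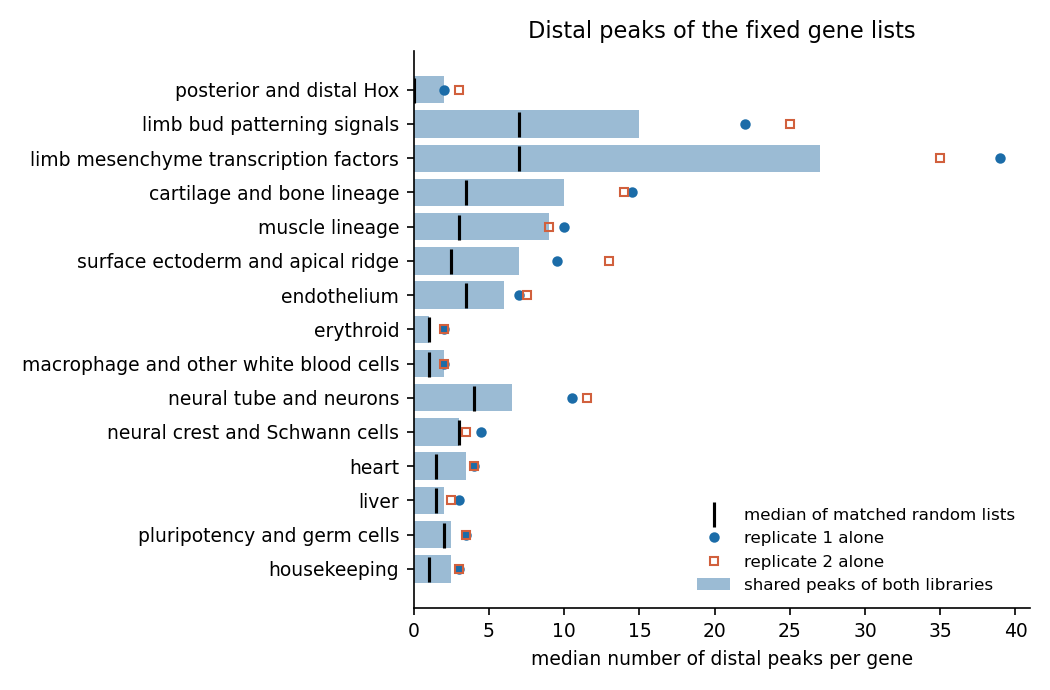
Median number of distal peaks per gene (x axis) in each fixed gene list (y axis), for shared peaks (bars), each library alone (points) and matched random lists (ticks). Limb mesenchyme transcription factors reach 27 against 7 in random lists, and erythroid genes 1 against 1.

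The posterior and distal Hox list had a median of 2 distal shared peaks against 0 (percentile 99.995). The percentile of distal peaks, posterior and distal Hox genes, was 67.3 when random lists were not matched on domain length. Within it Hoxa13, a determinant of the hand and foot plate, had 23 distal shared peaks (30.5 ± 7.78 in the libraries alone, SD, n = 2), Evx2, a homeobox gene beside the HoxD cluster, had 14 (18 in replicate 1 and 31 in replicate 2 alone) and Hoxc8 had 5. With hotspots in place of peaks Hoxa13 had 9, Evx2 6 and Hoxc8 4. Among peaks above the median signal they had 12, 12 and 5. Several counted peaks can lie in 1 hotspot, and a hotspot at Evx2 held 19 peaks of replicate 2. Housekeeping genes also stood above matched lists, with a median of 2.5 against 1 (percentile 99.745), with Ywhaz at 14 (25 and 18 in replicate 1 and replicate 2 alone) and Eef1a1, the translation elongation factor, at 10 (12 and 16). The percentile of distal peaks, housekeeping genes, fell inside the central 95% without matching (83.4), when all distal peaks within 50 kb were counted (81.4) and with hotspots (92.4).

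Lists of other cell types lay inside the central 95% of random lists, 4 of them close to its upper end. The limb mesenchyme list holds only transcription factors, while these lists mix such factors with other genes, such as Hbb-y, C1qa and Apoa1. Transcription factors had the highest counts in the neural, neural crest, heart and liver lists, but not in the endothelial and white blood cell lists. Gene class and cell type therefore cannot be told apart in this contrast. Endothelial genes had a median of 6 distal shared peaks against 3.5 (percentile 95.8), with Nrp1, a receptor of vascular growth signals, at 39 and the endothelial cadherin Cdh5 at 28. The percentile of distal peaks, endothelium list, passed the upper bound without matching (99.8), with hotspots (97.8) and with lists matched also on promoter peaks (98.3). Neural genes had a median of 6.5 against 4 (percentile 95.9), with the neural factors Pax6 at 43 and Sox2 at 32, and the percentile of distal peaks, neural tube and neurons list, passed the bound in replicate 2 alone (99.8), in replicate 1 alone (98.8), without matching (99.9) and among peaks above the median signal (98.6). Heart genes gave 3.5 against 1.5 (percentile 96.3), with the GATA factors Gata6 at 20 (42 and 24 in replicate 1 and replicate 2 alone) and Gata4 at 15 (26 in each), and the percentile of distal peaks, heart list, was 98.0 with hotspots. White blood cell genes gave 2 against 1 (percentile 95.3), with the leukocyte antigen Ptprc at 28 and Laptm5 at 7, and the percentile of distal peaks, macrophage and other white blood cells, was 99.3 with lists matched also on promoter peaks. Erythroid genes gave 1 against 1 (percentile 68.4), with Ank1, an ankyrin of the red cell membrane, at 6. Neural crest genes gave 3 against 3 (percentile 53.5), with Ets1 at 43 and Dct, a melanin enzyme, at 40. Liver genes gave 2 against 1.5 (percentile 79.3), with Foxa2 at 25 and Apob, the lipoprotein component, at 20. Germ cell and pluripotency genes gave 2.5 against 2 (percentile 75.8), with Prdm1 at 20 and Dazl at 4. Replicate 1 and replicate 2 alone gave medians of 10.5 and 11.5 for neural and of 2 in each for erythroid genes. For single genes they gave 64 and 55 for Nrp1, 43 and 37 for Cdh5, 42 and 61 for Sox2, 44 and 35 for Ptprc, 7 and 10 for Ank1, 67 and 58 for Ets1, 35 and 29 for Prdm1 and 6 and 8 for Dazl. Within 100 kb of a start the counts were 21 for Nrp1, 11 for Cdh5, 12 for Sox2, 7 for Gata6, 9 for Ptprc, 17 for Ets1, 11 for Dct, 6 for Foxa2, 11 for Apob and 12 for Prdm1. Pax6 kept 43 at this reach but had 8 among peaks above the median signal and 18 with hotspots. Nearest-start assignment does not show which gene a distal peak acts on.

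With assignment up to 500 kb, the 10 protein-coding genes with the most distal shared peaks genome-wide were Auts2 (118), Zfp608 (115), Zfhx3 (108), Lrmda (107), Nr2f2 (81), Rbms3 (81), Ntm (76), Tenm4 (74), Tcf7l2 (74) and Med13l (73). The sequence nearest to these genes was long, from 564 kb for Tcf7l2 to 1657.5 kb for Auts2, and counts of distal shared peaks of Zfhx3, Nr2f2, Ntm and Med13l within 50 kb were 21, 14, 18 and 13, below the 37 of both Lmx1b and Pax6. Within 50 kb Auts2 had 51, Lrmda 35, Tenm4 30, Zfp608 28, Tcf7l2 28 and Rbms3 19. Among peaks above the median signal Pax6 had 8 distal shared peaks and Lmx1b 50, and with hotspots they had 18 and 48. Replicate 1 and replicate 2 alone gave 180 and 164 for Zfhx3 and 129 and 118 for Nr2f2. Auts2, a regulator of neural development, lies on chromosome 5 from 131437333 to 132543344 (mm10), and 108 shared peaks fell inside the gene. Nr2f2, a nuclear receptor of mesenchyme and veins, spans 70351944 to 70366735 on chromosome 7 and had 6 shared peaks in its body. Across all 21938 protein-coding genes the median was 1 distal shared peak, and 4.08% had 20 or more. Med13l tied with another gene for the last of the 10 places, and ties went by more promoter peaks and then by alphabet.

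Promoters of limb transcription factors and signals were mostly open. A shared peak within 1 kb of a start was present for 34 of 35 limb mesenchyme transcription factors (97.1%, Wilson 95% interval 85.5 to 99.5) and for 23 of 25 patterning signals (92.0%, 75.03 to 97.8), against 66.5% of all protein-coding genes. These lists lay above all 10000 random lists and at percentile 99.8. All 18 housekeeping genes and 16 of 18 neural genes had a promoter peak (percentiles 99.955 and 98.0), and the percentile of promoter peaks, neural tube and neurons list, was 95.3 with a 500 bp window and 96.8 among peaks above the median signal. Shares were 85.0% for ectoderm, 80.0% for cartilage and bone, 73.3% for Hox, 64.3% for heart, 64.3% for neural crest, 55.6% for endothelium and 52.6% for muscle genes, all inside the central 95% of random lists. The percentile of promoter peaks, surface ectoderm and apical ridge genes, passed it with a 2 kb window (99.975) and in replicate 1 alone (99.8).

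Promoters of blood, liver and germ cell genes were less often open than those of random genes. A promoter peak was present for 3 of 18 white blood cell genes (16.7%, Wilson 95% interval 5.84 to 39.2) and 3 of 16 liver genes (18.8%, 6.59 to 43.0), both below all random lists. It was present for 5 of 14 germ cell and pluripotency genes (percentile 0.83) and 7 of 18 erythroid genes (percentile 1.04). In replicate 2 alone the percentile of promoter peaks, erythroid list, was 5.45, and in replicate 1 alone the percentile of promoter peaks, pluripotency and germ cells, was at the bound of 2.5. The percentile of promoter peaks, posterior and distal Hox genes, was 69.7 for shared peaks and 99.85 in replicate 2 alone, where all 15 genes of the list had a promoter peak.

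At Shh (ENSMUSG00000002633.4), the signal that sets the anterior to posterior axis of the limb (chromosome 5, 28456815 to 28467256, mm10), 8 distal and 0 promoter peaks were shared. Replicate 1 had 13 distal and 0 promoter peaks there, and replicate 2 had 25 and 3. Lmbr1 (ENSMUSG00000010721.15), whose introns hold a long-range limb enhancer of Shh, spans 29229802 to 29378390 on the same chromosome and contained 6 shared peaks. Intron 5 held 3 of them, at 29293316 to 29293465, 29314676 to 29314825 and 29315216 to 29315365. Their deposited signals were 81, 61 and 57 in replicate 1 and 65, 48 and 52 in replicate 2. Intron 9 held 2 shared peaks and intron 4 held 1.

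Replicates differed at the HoxD cluster, whose genes pattern the limb along its long axis. Replicate 1 had 33 peaks in the cluster (chromosome 2, 74668310 to 74765142) and replicate 2 had 74, of which 6 and 45 overlapped neither a peak nor a hotspot of the other library. Hoxd13, expressed in the distal limb, had no shared promoter peak, with 0 promoter peaks in replicate 1 and 1 in replicate 2. HoxC had 35 and 52 peaks and HoxB 48 and 65, while HoxA had 69 and 61. With 1 library on each side these differences could not be tested. The labels do not give the share of forelimb and hindlimb in either library, and they name 2 instrument models for replicate 2 and none for replicate 1.

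**Figure D3:**
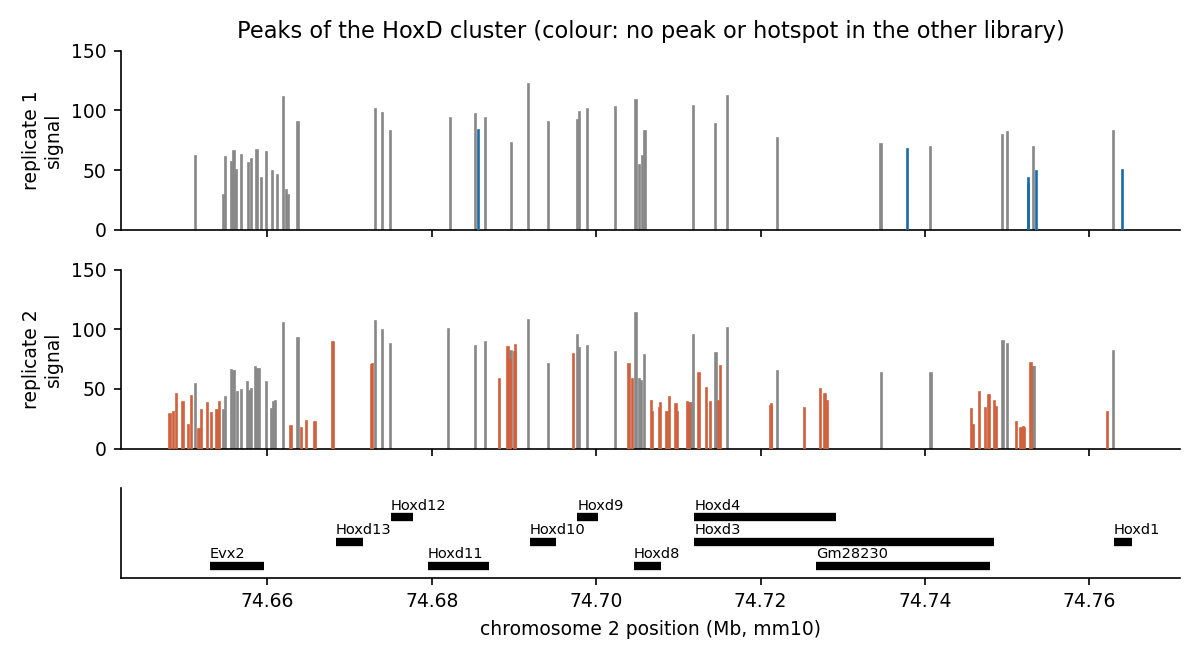
Peaks of both libraries (upper panels, height is deposited signal) and protein-coding genes (lower panel) along the HoxD cluster of chromosome 2. Coloured bars are peaks with no peak or hotspot in the other library, 6 in replicate 1 and 45 in replicate 2 between the ends of the cluster, some of which overlap in the drawing; outlines make bars slightly wider than the peaks.

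Such private peaks made up 22.1% of replicate 1 (38610 peaks) and 22.7% of replicate 2 (37971 peaks), or 22.4% on average over the 2 directions of 1 comparison. Private peaks ranked low, with median signal percentiles of 18.8 and 17.9. The share of peaks private to one library was 2.91% when only peaks above the median signal were counted, against all hotspots of the other library. Promoters held 8.56% and 11.1% of them and introns 45.7% and 42.4%. The private peaks with the highest signal lay near Hoxa11 (88), Nr2f1 (87) and Hoxd11 (84) in replicate 1, and near Hoxd13 (89) and, as a pair, Hoxd10 (87 and 85) in replicate 2. Nr2f1 encodes a nuclear receptor and the others are Hox genes. The Hoxd13 peak lay at 74667916 to 74668065 on chromosome 2, 319 bp from the start of the gene. The hotspots under these private peaks had a deposited −log10 q of 1.80 (Hoxa11), 4.17 (Nr2f1) and 1.64 (Hoxd11) in replicate 1. In replicate 2 it was 2.24 (Hoxd13) and, for the Hoxd10 pair, 2.12 and 3.09. Shared peaks with the same signal as private peaks above the median signal had a median at the ceiling of 100 in both libraries. The named private peaks were thus below the ceiling despite their high signal. Of all private peaks above the median signal, 15.4% in replicate 1 and 25.7% in replicate 2 were at the ceiling. Among shared peaks of the same signal the shares were 51.0% and 51.4%.

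The consensus site of CTCF, the insulator protein, was found in 6.76% of 90872 distal shared peaks (Wilson 95% interval 6.60 to 6.93) and in 0.111% of flanks 500 bp away, a ratio of 60.9, and the libraries alone gave 39.6 and 42.4. The REST site, bound by a repressor of neuronal genes, had a ratio of 101 (95% interval 32.3 to 318) that rests on 3 flank windows. Distal ratios were 2.34 for the E-box CAGCTG, 1.76 for the TWIST-like E-box bound by mesenchymal factors, 2.95 for an E-box beside a homeodomain site, 2.32 for GLI, 1.91 for TEAD, 13.1 for NFI, 2.98 for RFX and 2.71 for the epithelial factor GRHL. In the libraries alone the E-box beside a homeodomain site gave 2.66 ± 0.0564 (SD, n = 2). The GATA site, bound by blood and heart factors, was rarer in distal peaks than in flanks (0.441% against 1.19%, ratio 0.372, 95% interval 0.334 to 0.414). It was 1 of 5 words with a ratio and interval below 1 in distal peaks. The others were TP63 at 0.688 (0.609 to 0.776), PITX/OTX at 0.820 (0.792 to 0.850), LHX/LMX at 0.801 and the paired-type homeodomain dimer at 0.549. Against random windows of the same GC content GATA was at 0.384, TP63 at 0.694 and PITX/OTX at 0.903. LHX/LMX and the paired-type homeodomain dimer went above 1 with these windows, at 2.25 and 2.40, as did the control word at 1.92. The direction for these 2 sites therefore depended on the background.

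Of the 9 sites that reached a ratio of 1.5 in promoter peaks, 8 also did so in distal peaks, and NFY did not. Among 27765 promoter shared peaks the ratio to flanks was 8.09 for NRF1, 5.23 for ETS, 3.51 for NFY and 3.05 for SP/KLF, factors of CpG-rich promoters, and 8.24 for CTCF. Replicate 1 and replicate 2 alone gave 4.41 and 6.24 for NRF1 and 3.30 and 4.19 for ETS, and NFY was at 2.68 ± 0.115 (SD, n = 2). The TWIST-like E-box was at 0.877 and the E-box beside a homeodomain site at 1.02. Of 36 words searched, 1 of them the control word, 16 reached a ratio of 1.5 in distal peaks, and the control word did not. Several ratios depended on the background. The ratio of homeodomain sites was 1.09 in distal and 0.431 in promoter peaks against flanks, and 2.65 and 1.76 against random windows of the same GC content. With those windows the ratio was 125 for CTCF, 6.78 for the E-box beside a homeodomain site and 1.46 for GLI in distal peaks, and 24.6 for NRF1 in promoter peaks. The control word gave 1.28 (0.959 to 1.71) in distal peaks against flanks but 1.92 (1.31 to 2.83) against GC-matched windows. In promoter peaks it gave 0.745 (0.440 to 1.26) against flanks and 2.71 (1.14 to 6.46) against GC-matched windows, above the 1.76 of homeodomain sites.

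**Figure D4:**
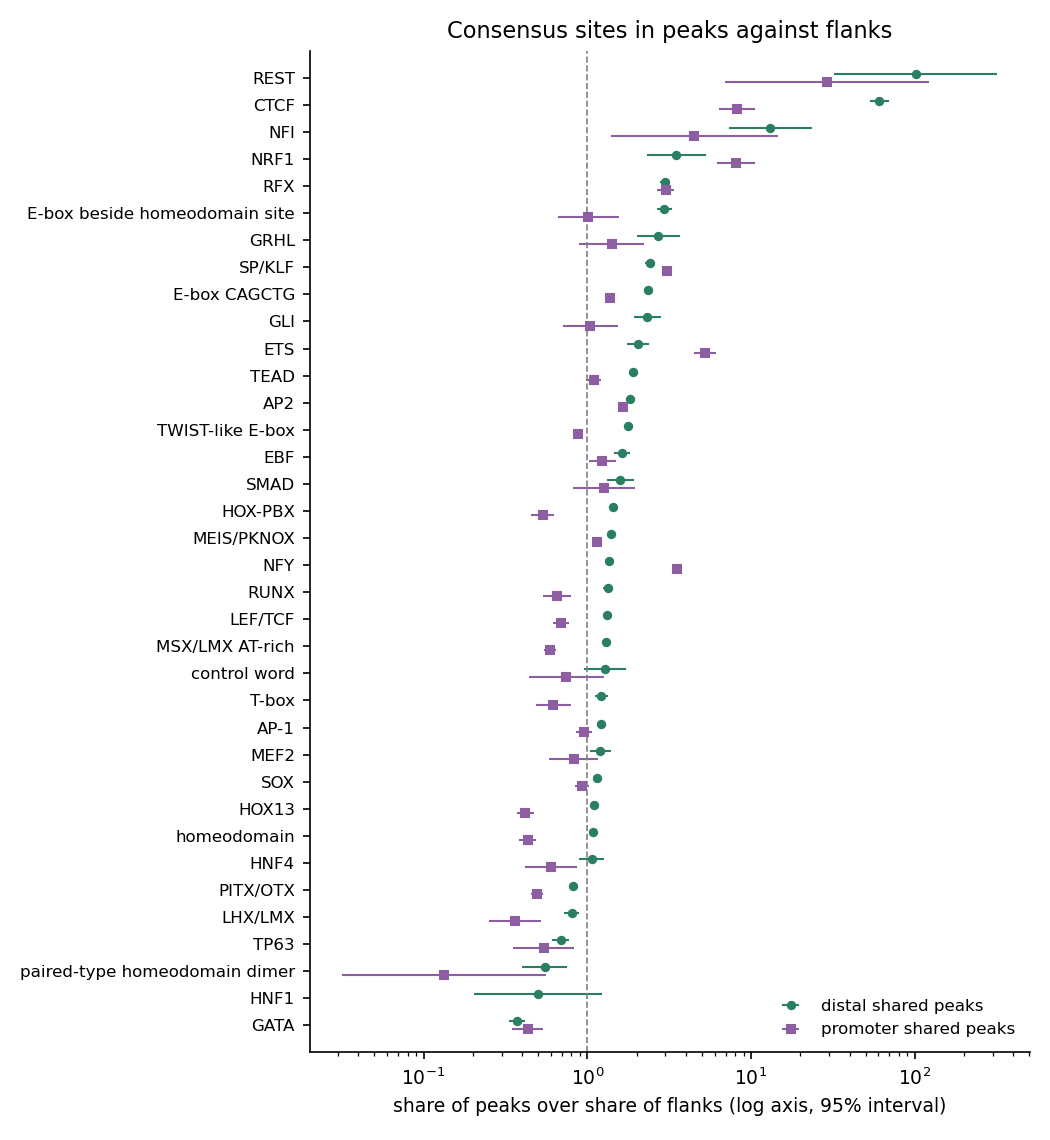
Share of shared peaks with a consensus site over the share of flanking windows (x axis, log scale), for distal and promoter peaks, with 95% intervals from counts. CTCF stands at 60.9 in distal and 8.24 in promoter peaks, and GATA at 0.372 and 0.431.

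The shared distal peaks with the highest signal lay near Grcc10, Nr4a1, Zmiz1, Zc3h4 and Scd3. The Zc3h4 peak lay 1036 bp from a start, close to the 1 kb limit of promoters, and the Zmiz1 peak 1523 bp. The Grcc10 peak lay in a coding exon, 4297 bp from a start. The peak near Nr4a1, an immediate early nuclear receptor, was intergenic at 101246376 to 101246565 on chromosome 15, with signals of 135 and 134. The widest hotspot of both libraries lay at Tnrc18 on chromosome 5 and was 11534 bp long in replicate 1 and 11406 bp in replicate 2. Id2, an inhibitor of helix-loop-helix factors, Ccnd2, a cyclin, Tgif1 and the retinoic acid degrading enzyme Cyp26b1 followed in replicate 1, and Evx2, Id2, Foxd1 and Ccnd2 in replicate 2. The Evx2 hotspot of 8648 bp was covered to 64.2% by hotspots of replicate 1, and the Foxd1 hotspot of 7308 bp to 49.7%.

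Embryos of both sexes were pooled, per the labels. Autosomes carried 40.5 to 66.7 shared peaks per Mb of called sequence, lowest on chromosome 14 and highest on chromosome 11. The X chromosome carried 17.2 per Mb and the Y chromosome 0.272. The density of X over the median autosome was 0.355, and 0.362 ± 0.00227 (SD, n = 2) in the libraries alone. Promoter peaks were present for 50.6% of X-linked and 67.8% of autosomal protein-coding genes.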

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

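Both tests of the private peaks in the first pattern and the test of decimal signals were chosen after related values had been seen, and the GATA tests before. Peaks outside the named chromosomes were part of no comparison and are given as values only. The mitochondrial sequence carried 31 peaks in replicate 1 and 34 in replicate 2, and unplaced or unlocalized sequences carried 150 and 147.

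Some peaks above the median signal were called in only 1 library, 2255 in replicate 1 and 2674 in replicate 2. An initial idea that these lie mostly in Hox clusters did not hold: 33 and 82 did (1.46% and 3.07%), though 16 and 19 of the 100 strongest of each library did. The share over all peaks was smaller. HoxA, HoxB, HoxC and HoxD held 69, 48, 35 and 33 of 174430 peaks in replicate 1. In replicate 2 they held 61, 65, 52 and 74 of 167369. Hox clusters were thus over-represented among these peaks without holding most of them. Calls near the threshold in locally open chromatin stay open: the median −log10 q was 3.34 (95% range over resampled regions 3.25 to 3.41), just above a bound of 3 that was set after values had been seen, but 15.4% and 25.7% were at the ceiling against 51.0% and 51.4% of shared peaks of the same signal, and medians of 4 and 6 other peaks lay within 10 kb against 3 and 2. Median GC differed by 5.33 percentage points between the libraries' strong private peaks (range 4 to 5.33), against a bound of 5, while the medians over all peaks were equal at 50.7%, and promoters held 10.7% of these peaks in replicate 1 and 24.2% in replicate 2, so a difference in base composition stays open and moves with the promoter share. No biological explanation was tested, because the labels give a single group.

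The GATA consensus was rarer in distal peaks than in the flanks, at a ratio of 0.372. Base composition does not account for it by itself: among 200 words of the same bases in another order, the percentile of GATA was 0 and the central 95% ran from 0.486 to 1.02. Simple repeats in the flanks do not either, since the ratio was 0.409 (95% interval 0.365 to 0.458) with soft-masked bases left out of the search. The reason stays open, and no biological explanation was tested, because the labels give a single group.

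Some peaks carry a signal written with a decimal, 5.48% of replicate 1 and 8.18% of replicate 2. Of these, 100% in both libraries lay on a hotspot that held the centre of no other kind of peak, which is consistent with a second step that adds a peak to a hotspot without one.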

How the results depend on the processing

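The alternatives without decimal-written peaks, with promoter-matched random lists and with other ratio limits were chosen after seeing the data. No paired analysis was possible because the labels give a single group. Unless stated, the cause was not tested. Among peaks above the median signal, peaks and hotspots per library gave 85449.5 peaks by construction, the percent of peaks shared between replicates was 82.6, the rank correlation of peak values between replicates 0.870, the percent of shared peaks near a transcription start 31.4, peaks private to one library 2.91%, the percent of peaks inside hotspots of the other library 97.1 (77.4 over all peaks) and the chromosome density of shared peaks: X over median autosome 0.261. The 82.6% counted only partners that were also above the median signal of their own library, while the 2.91% and the 97.1 were set against all hotspots of the other library. Against all peaks of the other library, sharing ran from 79.7% in decile 6 to 98.8% in decile 10 for replicate 1. For replicate 2 it ran from 85.0% to 98.9%. With 50% overlap of both peaks, sharing was 64.6% and the X ratio 0.352, and 73.0% of peaks lay by 50% in hotspots of the other library. Hotspots gave a sharing of 75.1% and a rho of 0.565. The observed sharing over chance placement was 36.9 with circular shifts and 12.3 with moves within 10 kb. Pearson r of log2 values was 0.906, and rho over distal peaks 0.879. The promoter share was 17.6% within 500 bp, 28.0% within 2 kb and 29.3% with starts of all genes, and 21.5% to 22.3% without either replicate. The X ratio was 0.360 to 0.363 without either replicate. Private peaks were 28.5% when hotspots were ignored and 15.4% when nothing lay within 500 bp. The number of lists high in distal peaks (7) ranged from 6 to 9. Of 210 list values 190 kept their side of the central 95% and 0 crossed to the opposite side, and of 441 motif ratios 397 kept their call. Against GC-matched windows 17 of the 36 words reached 1.5 in promoter peaks with an interval above 1, the control word among them, and 10 calls reversed: in distal peaks the paired-type homeodomain dimer (2.40) and LHX/LMX (2.25), in promoter peaks homeodomain (1.76), HOX13 (1.76), HOX-PBX (1.74), MEIS/PKNOX (0.846), LEF/TCF (1.26), MSX/LMX (1.90), LHX/LMX (2.13) and HNF4 (2.12). The control word in promoter peaks went from 0.745 to 2.71 with the same windows, above each of these promoter ratios. Of 350 recomputed counts of distal peaks at named genes, 143 moved by more than 1.5 times. Depth is unknown, so its effect on the weak peaks was not assessed.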

Other observations

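The families, genes and spacing test below were chosen after values had been seen. Families defined by symbol differed widely in promoter accessibility. A shared promoter peak was present for 19 of 1135 olfactory receptor genes (1.67%), 3 of 331 vomeronasal receptor genes (0.906%) and 8 of 49 genes of cytochrome P450 family 2 (16.3%). It was present for 48 of 50 proteasome subunit genes (96.0%), 88 of 98 ribosomal protein genes (89.8%) and 344 of 394 Zfp genes (87.3%). Wnt genes had a median of 8 distal shared peaks against 3 in matched random lists (percentile 99.985) and Sox genes 11 against 4 (percentile 99.75), while Fgf genes had 3 against 3 (percentile 56.5).

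Private distal peaks of some lists were more numerous in replicate 2, at 11 in replicate 1 against 40 in replicate 2 for Hox, 66 against 153 for ectoderm, 65 against 142 for neural and 68 against 131 for muscle genes, while private distal peaks over all genes numbered 33957 against 32310. Single genes were picked for large differences. Lhx2, a limb outgrowth factor, had 43 distal peaks in replicate 1 and 17 in replicate 2, and Olig2, a motor neuron progenitor factor, had 27 and 7. Dlx6, a homeobox gene of the apical ridge, had 8 and 45, Mnx1, a motor neuron factor, had 5 and 31, and Tbx2, a T-box repressor, had 5 and 26. Dlx6 is in the ectoderm list and Mnx1 and Olig2 are in the neural list, so single loci can weigh on these sums in either direction. With 1 library on each side no difference was tested, and the labels do not give the share of forelimb and hindlimb in either library.

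Pairs of an E-box and a homeodomain site were compared by the gap between them in distal peaks. The ratio of peaks to flanks was 3.02 at gaps of 3 to 7 bases and 2.06 at gaps of 9 to 20, so the near gaps stood 1.46 times higher (95% interval 1.28 to 1.67), more than separate enrichment of the 2 sites would give. The excess rests on a gap of 4 bases, with a ratio of 5.44 (446 peaks), against 1.38 to 2.61 at the other gaps of the 21 compared. Without that gap, near over far was 0.989 (0.844 to 1.16).

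CTCF sites were not most frequent in the strongest distal peaks. They were found in 1.98% of distal peaks in the lowest decile of shared peaks by signal, in 17.0% in decile 9 and in 7.31% in decile 10. Promoter peaks made up 77.9% of decile 10, which left 2627 distal peaks against 8210 in decile 9. Distal was judged on protein-coding starts only, so starts of other genes can be among these peaks.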
